A study of Homo sapiens with 14 samples.

How the data were processed

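Polyadenylated RNA was measured by sequencing in 14 libraries that form 7 groups of 2. SIGM5, an acute myeloid leukaemia line, was treated with DMSO or with 12.5 µM TETi76, a compound described in the series as an inhibitor of TET dioxygenases. K562, an erythroleukaemia line, was used as the clones K01, TET2+/+ in the series text, and K18, TET2-/-. K01 received DMSO, 12.5 µM TETi76, 100 µM ascorbate, or TETi76 with ascorbate, and K18 received DMSO only. Treatment lasted 24 h. Group membership came from the sample labels. The labels number the replicates but do not say whether they were separate cultures, so every p-value here measures a spread between libraries that may be technical. TET2 genotype and clone cannot be separated, since each genotype was 1 clone.

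The deposited SIGM5 values were raw read counts per gene, all whole numbers. The deposited K562 values were fragments scaled by gene length and library size (FPKM), although the matrix was named as counts. The quantifier was not named, and FPKM cannot be told apart from the single-read form RPKM. The authors' notes named the hg19 genome, the aligner STAR without a version, edgeR 3.24.3 and limma 3.38.3, without saying which made which table. Genes were identified by symbol alone. The planned analysis had assumed counts in both lines; the K562 plan was changed once its values were seen. The value of 1 read in each K562 library was found from values at an FPKM of up to 0.15. Among 4986 low K562 values of 1160 genes, 87.0% were whole multiples of that value, within 0.02 of a read. After random scaling 5.6% were. In both, the lowest value of a gene was taken as whichever small number of reads gave more whole multiples.

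SIGM5 library totals ran from 18893636 to 23639198 counts. K562 totals are not printed in its table. From the value of 1 read in 130 genes with a single transcript, their depth was estimated at 4.71 to 8.96 M reads (M, mega), an approximation that depends on assumed gene lengths. The SIGM5 table held 19196 genes and that of K562 held 26171, with 19087 shared symbols. Single-sample values equalled the matrix columns in all 10 K562 and all 4 SIGM5 libraries, and 0 columns were left unused. In K562, 26 entries with a number in place of a gene name, at most 0.0657% of any library's FPKM sum, were left out. A further 2304 short-RNA entries were left out of the tests because a poly(A) library with length scaling gives them extreme values. MIR6723 and MIR4461 alone took 29.64% to 36.41% of the FPKM sum. Pearson correlations between replicates on the log2 scale were at least 0.9711 in K562 and 0.9927 in SIGM5.

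SIGM5 counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr), which left 11340 genes. K562 values were tested with limma 3.58.1 (trend, robust) on log2(FPKM + 1) in 1 fit of 5 groups and 10 libraries, for 12527 genes with an FPKM of at least 1 in at least 2 libraries. This pseudocount understates the fold change of genes near an FPKM of 1. The contrasts were TETi76 against DMSO in each line, K18 against K01 in DMSO, ascorbate against DMSO, TETi76 with ascorbate against ascorbate, TETi76 with ascorbate against TETi76, and the interaction of TETi76 with ascorbate. The difference between lines was that of the separately fitted TETi76 effects, with Satterthwaite degrees of freedom, over 9741 genes tested in both. All tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Log2 values have standard errors (SE); group means are given ± SD with n = 2, in library-scaled counts (CPM) for SIGM5 and FPKM for K562.

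The comparisons, thresholds, 27 gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named, in the TETi76 comparisons of SIGM5 and K01 and in K18, up to 5 called genes per direction with the largest log2 change, a mean of at least 10 CPM or FPKM in the higher group and no overlap between groups. It named 3 per direction elsewhere, up to 4 called members of each list or, where none was called, 2 abundant members, and TET1, TET2 and TET3. Unnamed, antisense and short RNA loci were passed over. Some eligible genes are not reported here.

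The lists were: DNA methylation machinery; 2-oxoglutarate-dependent histone demethylases; NRF2 targets; integrated stress response (ATF4) targets; endoplasmic reticulum chaperones; heat shock; p53 targets; BCL2 family. Further lists covered NF-kB and TNF response, interferon response, immediate early genes, DNA replication and S phase, mitosis, MYC and ribosome biogenesis, cholesterol synthesis, hypoxia targets, iron handling and metallothioneins. Identity lists covered erythroid, megakaryocyte, myelomonocytic, stem and progenitor, germline, lymphoid and stromal, endothelial or epithelial genes. The remaining lists were mitochondrially encoded genes, of which 0 are in either table, and nuclear oxidative phosphorylation genes. Lists with at least 3 measured members were tested against other genes with camera at a preset correlation of 0.01. They were tested again with the correlation estimated from the data. That second form takes its degrees of freedom from the residuals of the fit, few in K562 and fewest in SIGM5, rather than from the number of genes. A list can therefore lose its call there without correlated genes. The difference between lines used cameraPR, which takes no estimated correlation. fry was run as an alternative.

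Similarity between profiles was measured across genes, which are not independent replicates. Profiles that share the K01 DMSO libraries were set against 100 simulated draws of unchanged groups. Power was tested on simulated data with the same spread. In SIGM5 64.2% of genes changed 1.5-fold, 89.2% changed 2-fold and 95.2% changed 4-fold were recovered. The shares were 46.3%, 74.6% and 87.9% for TETi76 in K01, and 16.4%, 38.8% and 92.4% for the interaction. At most 5.26% of calls were false in the 6 comparisons simulated. The simulated values followed the fitted model of each test, with genes independent, so a low false share was largely built in. Far fewer genes were changed than in the data, with 142 simulated calls for TETi76 in K01 against 2919, so the recovered shares need not carry over. TETi76 with ascorbate against either compound alone was not simulated. Alternatives covered filters, pseudocounts, scaling, blocking by replicate number, thresholds, DESeq2 1.42.0, limma-voom and leaving out each library. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.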

Results

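Messenger RNA was profiled after 24 h of treatment in SIGM5 leukaemia cells and in K562 clones that differ in TET2 genotype. The question in the series text was what inhibition of TET dioxygenases does to gene expression in these lines. SIGM5 had 2 DMSO and 2 TETi76 libraries. K01 had 2 libraries each for DMSO, TETi76, ascorbate and TETi76 with ascorbate, and K18 had 2 DMSO libraries. SIGM5 totals were 18893636 and 21569319 counts for DMSO and 23639198 and 22897513 for TETi76. Estimated K562 depths were 8.96 and 6.82 M reads (M, mega) for K01 DMSO, 7.59 and 8.68 for K18, 7.05 and 7.3 for TETi76, 6.92 and 6.47 for ascorbate and 4.71 and 6.87 for TETi76 with ascorbate.

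In SIGM5 the quinone reductase NQO1, a target of the oxidative stress factor NRF2, rose from 7.44 ± 0.259 to 57.1 ± 1.85 CPM under TETi76 (log2 2.94, SE 0.14, adjusted p = 6.44e-12, n = 2 per group). The ferritin chains FTL (log2 1.13, SE 0.09) and FTH1 (log2 1.10, SE 0.10), which store iron, rose too. Transcripts of the metalloprotease ADAM8, the kinase SGK1 and the inflammatory cytokines IL1B and CXCL8 rose by log2 2.02, 1.67, 1.63 and 1.61. IL1B reached 35.2 ± 5.56 CPM from 11.4 ± 1.25, and CXCL8 reached 209 ± 25.8 from 68.3 ± 21.9 (adjusted p = 0.0112). The myeloid integrin ITGAM rose by 1.36 (SE 0.14), whereas CTSG, a granule protease of immature myeloid cells, fell by 1.28 (SE 0.17) on the log2 scale. The interferon-induced genes IFIT1 (log2 -2.86, SE 0.47), IFIT3 (log2 -1.96, SE 0.35), MX1 (log2 -1.77, SE 0.29) and MX2 (log2 -1.36, SE 0.18) fell, IFIT1 from a low 2.05 ± 0.137 CPM. The metal-binding proteins MT1H (log2 -1.54) and MT1G (log2 -0.98), the ligand WNT7B (log2 -1.57) and the phosphatase PTPN3 (log2 -1.33) fell. TET2 stood at 40.9 ± 2.36 against 39.2 ± 1.33 CPM (log2 0.06, adjusted p = 0.863), TET3 at log2 0.04 (adjusted p = 0.892) and TET1 at log2 -0.80 (adjusted p = 0.0707). TET1 passed the threshold without DMSO replicate 1 (adjusted p = 0.0325).

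edgeR called 468 of 11340 genes in SIGM5, 293 higher and 175 lower, and 106 of them changed at least 2-fold. This count depended on which libraries set the spread. Leaving out 1 library left the spread to be estimated from the 2 libraries of the other group alone. The count then rose without either DMSO library and fell without either TETi76 library. These shifts do not show that single libraries carried the effects. Across genes, the differences between replicates 1 and 2 in DMSO and in TETi76 correlated at -0.24, as if DMSO replicate 1 paired with TETi76 replicate 2. With that crossed pairing as a block, chosen after the data were seen, 1291 genes were called, including all 468. The labels give no such pairing.

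Among the fixed lists in SIGM5, 9 of 17 NRF2 targets rose (10 adjusted over the list alone), with a median log2 change of 0.45. The camera test gave adjusted p = 3.21e-23 at the preset correlation and adjusted p = 0.14 with an estimated correlation. NF-kB targets had 6 of 17 members higher (7 adjusted over the list alone, median 0.53), and the interferon list 7 of 22 lower (13 adjusted over the list alone, median -0.60). The NF-kB median was 0.34 with a filter of 1 CPM in 2 libraries, and the interferon count was 12 without a filter on low counts. Cholesterol synthesis had 4 of 22 lower (8 over the list alone, median -0.27), FDPS falling by 0.69 (SE 0.10), and mitosis 1 of 22 lower (7 over the list alone, median -0.24). Each of these 4 lists passed at the preset correlation and had adjusted p = 0.14 with an estimated correlation. Metallothioneins had 5 of 8 members lower and iron handling 3 of 12 higher (adjusted p = 0.22 and 0.183 with an estimated correlation). Immediate early genes, which growth signals induce, had 6 of 24 higher, DUSP6 and SPRY4 among them at log2 0.99 and 0.90, and DNA methylation genes 2 of 19 lower (adjusted p = 0.251 for each list with an estimated correlation). The integrated stress response list had 1 member higher and 2 of 23 lower (1 and 6 adjusted over the list alone), the heat-shock list 1 of 16 higher (5 over the list alone), and oxidative phosphorylation 0 of 19 called by edgeR, with 6 at an unadjusted p under 0.05. Those 3 passed at the preset correlation and had adjusted p = 0.4, 0.289 and 0.4 with an estimated correlation. Of 12 lists called at the preset correlation, 0 were called with an estimated correlation. For NRF2 targets the estimated correlation was -0.0575, below the preset 0.01, yet the unadjusted camera p went from 1.28e-24 to 0.00808. That loss reflects the few degrees of freedom of the test. The estimate was also below 0.01 for NF-kB targets (-0.00919), DNA methylation (-0.0141), mitosis (-0.0167), cholesterol synthesis (-0.0178), heat shock (-0.0662) and iron handling (-0.0762). It was above 0.01 for interferon (0.0327), the integrated stress response (0.0718), immediate early genes (0.114), oxidative phosphorylation (0.233) and metallothioneins (0.332).

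Remaining SIGM5 lists did not pass camera. Myelomonocytic genes had 5 members higher and 6 lower of 22, p53 targets 1 higher of 20, the BCL2 family 1 higher and 1 lower of 13, S phase 1 lower of 25 and endoplasmic reticulum chaperones 2 higher of 16. Hypoxia, erythroid and megakaryocyte lists had 1 member higher each and lymphoid markers 1 lower. edgeR called 0 of 18 histone demethylases, 0 of 22 MYC and ribosome biogenesis genes, 0 of 6 stem and progenitor genes and 0 of 8 stromal genes, with 2, 3, 2 and 0 at an unadjusted p under 0.05. The germline list had 1 measured member and was not tested. Median and mean differed in sign for p53 targets, the BCL2 family, erythroid and myelomonocytic genes. Counts of called members moved with single libraries. Without TETi76 replicate 1 and without TETi76 replicate 2 they were 4 and 4 for NRF2 targets, 2 and 2 for immediate early genes, 1 and 1 for cholesterol synthesis and 3 and 3 for metallothioneins. They were 1 and 2 for higher and 1 and 3 for lower myelomonocytic genes, and 0 and 0 for DNA methylation by edgeR (3 and 3 unadjusted). The interferon count was 11 without DMSO replicate 2 and 4 without TETi76 replicate 2, and the cholesterol count was 7 and 9 without DMSO replicates 1 and 2. Without those DMSO libraries, in that order, mitosis had 8 and 4 lower members, the stress response list 5 and 4 lower and the heat-shock list 4 and 4 higher, and DNA methylation had 4 lower without DMSO replicate 2.

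**Figure D1:**
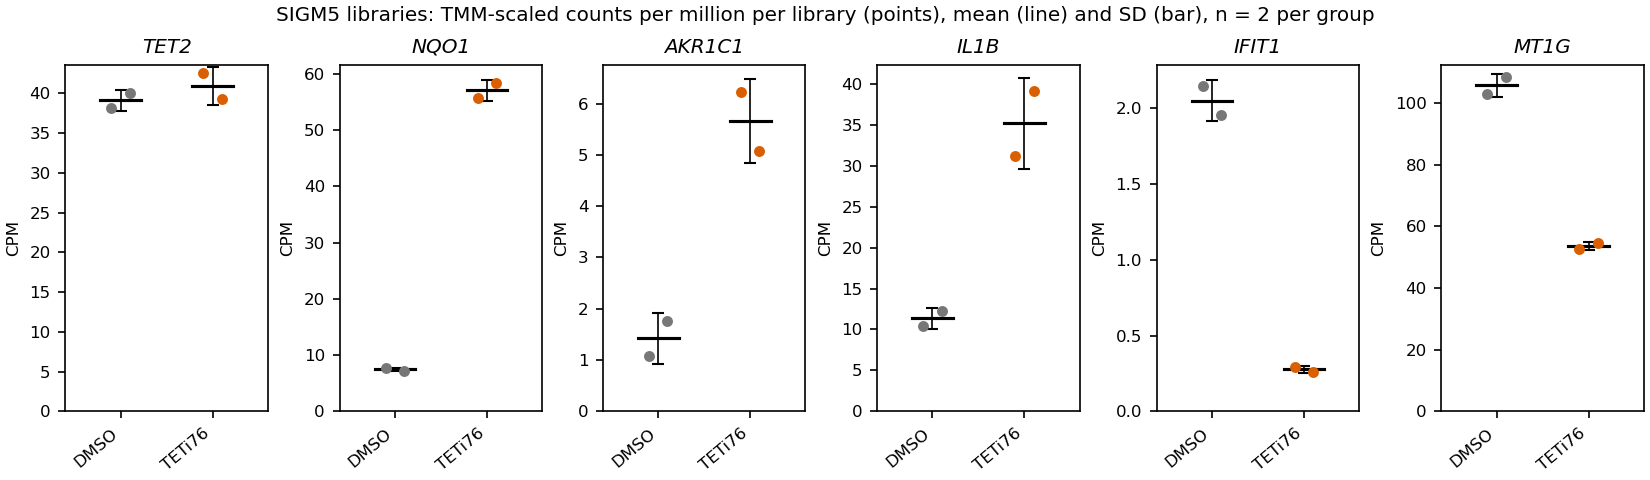
Expression in CPM of 6 genes in the 2 DMSO and 2 TETi76 libraries of SIGM5, with points for libraries, bars for the mean and whiskers for the SD. NQO1, AKR1C1 and IL1B were higher and IFIT1 and MT1G lower under TETi76, while TET2 was not called.

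In K01 cells TETi76 raised OSGIN1, a growth regulator induced by oxidative stress, from 2.85 ± 0.365 to 48.2 ± 2.14 FPKM (log2 3.68, SE 0.17, adjusted p = 1.31e-06, n = 2 per group). The autophagy receptor SQSTM1 rose by log2 2.65 (SE 0.07) to 357 ± 2.21 FPKM, the uridine phosphorylase UPP1 by 2.74 (SE 0.29) and the stress gene GADD45B by 2.67 (SE 0.26). The long noncoding RNA LUCAT1 was listed at 0 in DMSO and reached 11.4 ± 1.58 FPKM. CHAC1, which degrades glutathione, fell from 39.7 ± 4.26 to 1.86 ± 0.42 FPKM (log2 -3.83, SE 0.17, adjusted p = 1.2e-06). It is a target of ATF4, the transcription factor of the integrated stress response. DDIT4, an inhibitor of mTORC1, fell from 439 ± 2.61 to 46.7 ± 0.204 FPKM, and PSAT1, a serine synthesis enzyme, from 156 ± 0.883 to 20.2 ± 0.975. Their log2 changes were -3.21 (SE 0.10) and -2.88 (SE 0.09), and those of INHBE and PLCD1 were -3.34 and -2.61. limma called 2919 of 12527 genes, 1203 higher and 1716 lower, of which 513 changed at least 2-fold. Scaling shifted this split, to 1350 and 1501 with median-ratio scaling and to 1428 and 1382 with quantile normalization. The count was 1677 and 1663 without K01 DMSO replicates 1 and 2, and 1779 and 1765 without TETi76 replicates 1 and 2.

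**Figure D2:**
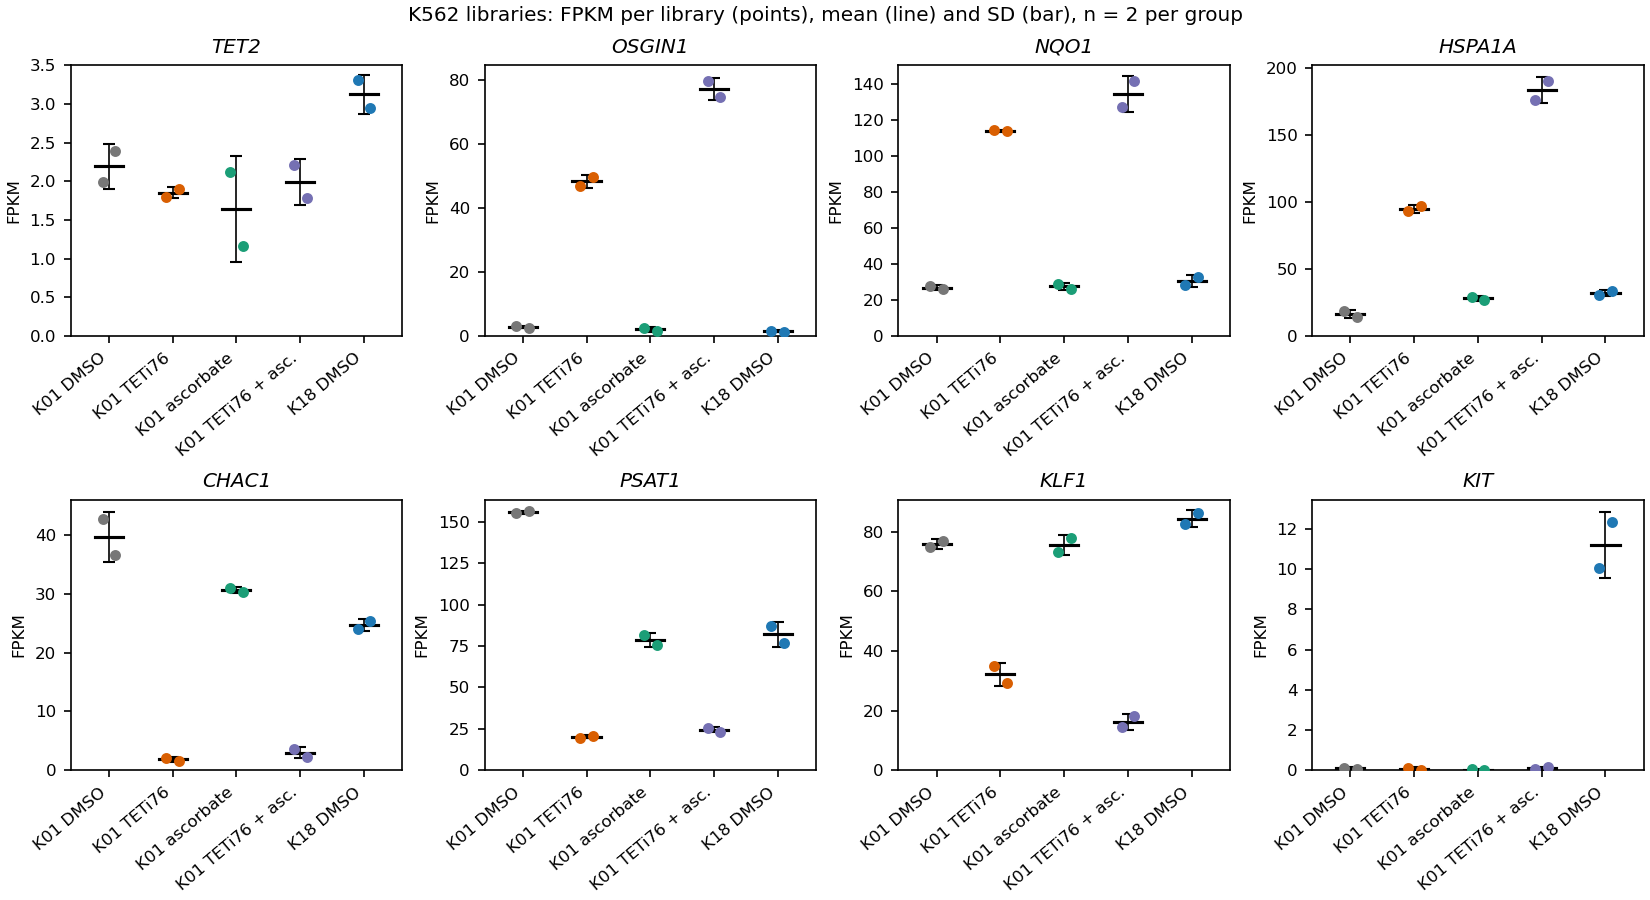
FPKM of 8 genes in the 5 K562 groups of 2 libraries, with points for libraries, bars for the mean and whiskers for the SD. OSGIN1, NQO1 and HSPA1A were higher and CHAC1, PSAT1 and KLF1 lower in both TETi76 groups than in their own controls, and KIT was above 10 FPKM in K18 alone.

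Of the lists in K01, 20 of 23 integrated stress response targets fell under TETi76 and 1 rose (median -1.42, adjusted p = 1.62e-17 by camera and 0.00482 with an estimated correlation). NRF2 targets rose in 14 of 19 members and fell in 2 (median 0.98, adjusted p = 0.0139 with an estimated correlation), led by OSGIN1, NQO1 (log2 2.04, SE 0.09), AKR1C1 (1.57) and GCLC (1.33), which makes glutathione. S phase genes fell in 20 of 25 members (21 adjusted over the list alone, median -0.51, adjusted p = 0.0175 with an estimated correlation). The replication helicase subunit MCM7 fell from 215 ± 1.72 to 72.8 ± 1.14 FPKM and CDC45 fell by 1.35 (SE 0.08). Immediate early genes rose in 12 of 20 (15 over the list alone) and heat-shock genes in 8 of 17 with 1 lower (10 over the list alone), with adjusted p = 0.0139 and 0.0212 with an estimated correlation. The chaperone HSPA1A rose from 16.2 ± 2.99 to 94.8 ± 2.69 FPKM, although reads of HSPA1A and HSPA1B cannot be fully separated. Cholesterol synthesis fell in 14 of 23 and rose in 1, erythroid genes fell in 12 of 22, and stromal or epithelial markers rose in 4 of 6, each with adjusted p = 0.0365 with an estimated correlation. The erythroid factor KLF1 fell (log2 -1.22, SE 0.12), and the filament protein VIM rose by 1.29 (SE 0.06). Oxidative phosphorylation fell in 12 of 23 (14 over the list alone, adjusted p = 0.0443 with an estimated correlation). These 9 lists passed at both correlations. Without DMSO replicate 2 the cholesterol count was 9 and the erythroid count 7. The cholesterol count was also 9 without TETi76 replicate 1, and the erythroid count 7 without TETi76 replicate 2.

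Lists that did not pass camera in K01 still held called genes. The DNA methylation list had 2 members higher and 5 lower of 19. IDH1 and IDH2, which make the TET cofactor 2-oxoglutarate, fell (log2 -1.77, SE 0.09, and -1.03, SE 0.08), as did the maintenance methyltransferase DNMT1 (log2 -0.48, SE 0.06). The p53 targets had 4 higher and 5 lower of 18, with the cell-cycle inhibitor CDKN1A at log2 1.66 and the death gene BBC3 at log2 -1.96. Histone demethylases had 3 higher and 1 lower of 18, endoplasmic reticulum chaperones 3 and 4 of 16, the BCL2 family 2 and 2 of 13, NF-kB 4 and 1 of 13, mitosis 3 and 5 of 22, and MYC and ribosome biogenesis 5 and 4 of 22. Hypoxia targets had 6 higher and 2 lower of 21, iron handling 3 and 1 of 13, megakaryocyte genes 1 and 3 of 8, and stem and progenitor genes 1 and 3 of 8. Interferon and metallothionein lists had 2 members higher each, myelomonocytic and germline lists 1 each, and limma called 0 of 4 lymphoid markers, with 1 at an unadjusted p under 0.05. Without DMSO replicates 1 and 2 and TETi76 replicates 1 and 2, in that order, the higher members were 2, 1, 2 and 2 for NF-kB and 2, 3, 2 and 2 for MYC and ribosome biogenesis. Hypoxia targets had 3 higher without TETi76 replicate 2, and mitosis had 3 lower without DMSO replicate 1 or TETi76 replicate 2. FTL and FTH1 rose by 1.71 (SE 0.04) and 1.13 (SE 0.05). Median and mean differed in sign for demethylases, chaperones, p53 targets, the BCL2 family and NF-kB, and the mitosis test pointed down with both positive. TET2 stood at log2 -0.16 (adjusted p = 0.65), TET3 at -0.20 (adjusted p = 0.398) and TET1 at -0.40 (adjusted p = 0.0552).

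K18 was set against K01 in DMSO to ask what distinguishes the TET2-/- clone. The germline genes ACTL8 (25.4 ± 0.521 against 0.188 ± 0.266 FPKM, log2 4.49, SE 0.25, adjusted p = 8.99e-06) and SSX3 (log2 4.29), the eosinophil protein PRG2 (log2 4.09), TUBA3C (log2 4.46) and the meiotic kinase AURKC (log2 4.04) were higher in K18. The secretory protein SCG3 (log2 -4.35, SE 0.08), CTAG2 (log2 -4.16), the leukocyte phosphatase PTPRC (log2 -3.96) and SOX5 (log2 -3.39) were lower. The stem cell factor receptor KIT stood at 11.2 ± 1.62 against 0.0902 ± 0.0498 FPKM (log2 3.48, SE 0.23), and embryonic globin HBE1 at 1244 ± 15.1 against 4629 ± 222 (log2 -1.89, SE 0.04). TET2 mRNA was 3.13 ± 0.256 FPKM in the libraries labelled TET2-/- and 2.19 ± 0.289 in K01 (log2 0.37, SE 0.22, adjusted p = 0.314). TET1 and TET3 stood at log2 0.04 (adjusted p = 0.9) and -0.05 (adjusted p = 0.871). A transcript level does not test a disruption that leaves the transcript in place. limma called 1888 genes, 859 higher and 1029 lower in K18, of which 504 differed at least 2-fold, 314 higher and 190 lower. The larger number of lower calls depended on the scaling: median-ratio scaling gave 928 higher and 893 lower, and quantile normalization 833 and 828. The count was 967 and 874 without K01 DMSO replicates 1 and 2, and 897 and 783 without K18 replicates 1 and 2.

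Integrated stress response targets were lower in K18 for 14 of 23 members (17 adjusted over the list alone, with 1 higher), with PSAT1 at log2 -0.92 (SE 0.09) and a list median of -0.41. This was the 1 list of 7 called at the preset correlation that passed with an estimated correlation (adjusted p = 0.0459). Its count of lower members was 8 and 9 without K01 DMSO replicates 1 and 2, and 7 and 7 without K18 replicates 1 and 2. Erythroid genes were lower for 13 of 22 and cholesterol synthesis genes for 10 of 23 with 1 higher (adjusted p = 0.0831 each with an estimated correlation). The erythroid count was 8 and 8 without the K01 replicates and 7 and 7 without the K18 replicates. Cholesterol synthesis had 6 lower members without K01 DMSO replicate 2 and 4 without K18 replicate 1. Mitosis had 8 of 22 lower, S phase 7 of 25 lower, the germline list 5 higher and 1 lower of 11, and oxidative phosphorylation 1 higher and 3 lower of 23 (adjusted p = 0.22 each with an estimated correlation). S phase had 2, 1, 3 and 1 lower members without K01 DMSO replicate 1, K01 DMSO replicate 2, K18 replicate 1 and K18 replicate 2. DNMT3B was lower (log2 -0.42, SE 0.08, adjusted p = 0.0076), but not without K01 DMSO replicate 1 (0.0538) or K18 replicate 2 (0.0554). The growth-induced factor EGR1 was lower by log2 -1.92 (SE 0.09).

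Whether TETi76 in K01 resembled the TET2-/- clone was examined across genes. The TETi76 and K18 profiles correlated with Pearson r = 0.28 and Spearman rho = 0.34 over 12527 genes, but both used the K01 DMSO libraries. Simulated unchanged groups with shared controls gave r from 0.47 to 0.53, and their covariance averaged 0.0264 against 0.0683 observed. With TETi76 plus ascorbate against ascorbate, which shares no library with K18 against K01, r was 0.12 and rho 0.16, against simulated r from -0.04 to 0.05. The simulated genes varied independently, so these ranges do not cover genes that vary together. Among genes called in both of those, 174 were higher in both and 429 lower in both, where independence gives 110.3 and 183.3, and 115 and 146 went opposite ways, where it gives 132.2 and 153.1. TETi76 profiles in K01 with and without ascorbate had r = 0.68, and those in K01 and SIGM5 had r = 0.27 over 9741 genes. Genes are not independent replicates, so no p-value is attached.

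**Figure D3:**
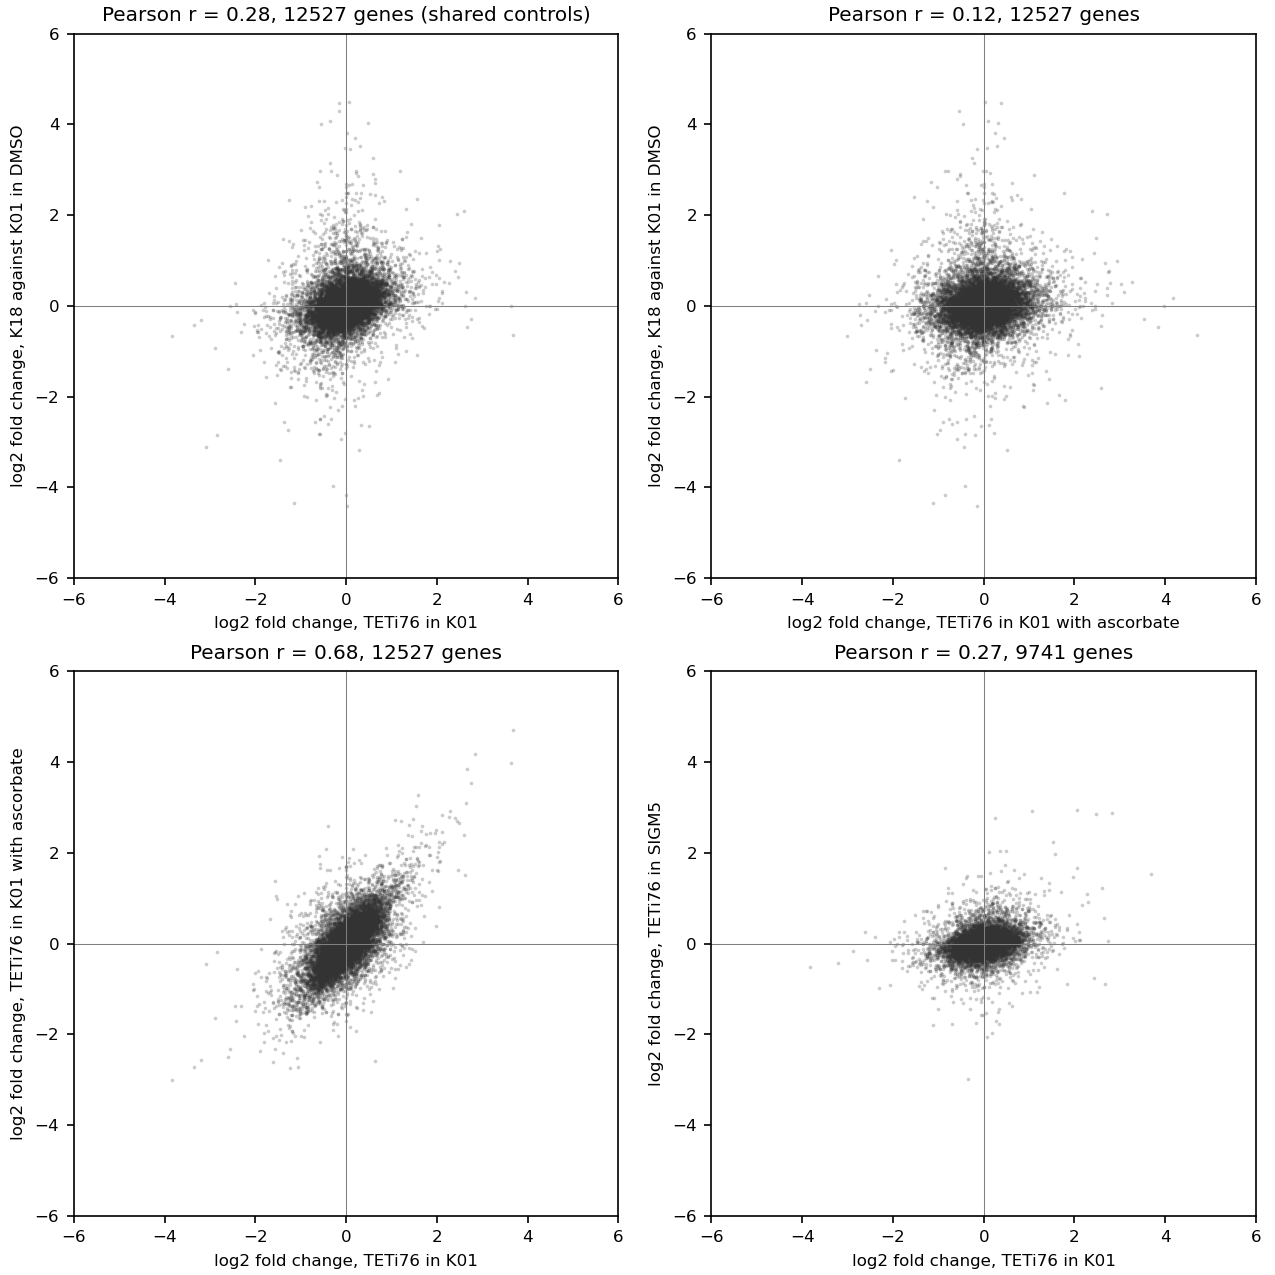
Log2 fold changes of every tested gene in 4 pairs of comparisons, 1 point per gene, both axes in log2 units. Pearson r was 0.28 for TETi76 and K18 with shared controls, 0.12 for TETi76 with ascorbate and K18 without a shared library, 0.68 for TETi76 without and with ascorbate, and 0.27 for K01 and SIGM5.

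Ascorbate, a cofactor of TET and other dioxygenases, was given alone to K01. It lowered the transsulfuration enzyme CTH from 26.6 ± 1.17 to 12.5 ± 1.71 FPKM (log2 -1.04, SE 0.14, adjusted p = 0.0208), PSAT1 from 156 ± 0.883 to 78.6 ± 4.50 (log2 -0.98, SE 0.09) and ATF5 (log2 -0.98, SE 0.16). EGR1 (log2 0.87, SE 0.09), ACSM3 (log2 0.83, SE 0.09) and ARHGAP25 (log2 1.01, SE 0.17) rose. Integrated stress response targets fell in 9 of 23 members (19 adjusted over the list alone, median -0.50, adjusted p = 0.00159 with an estimated correlation). Heat-shock genes rose in 2 of 17 (5 over the list alone), HSPA8 by 0.40 (SE 0.04), and cholesterol synthesis in 1 of 23 (10 over the list alone), HMGCS1 by 0.61 (SE 0.08), each with adjusted p = 0.0277 with an estimated correlation. The germline list had 1 higher of 11 (adjusted p = 0.288 with an estimated correlation). TET1, TET2 and TET3 stood at log2 0.15, -0.30 and -0.08 (adjusted p = 0.712, 0.659 and 0.886). limma called 60 genes, 21 higher and 39 lower, with 1498 at an unadjusted p under 0.05. These calls rested on every library: the counts were 0 without DMSO replicate 1 (1180 unadjusted), 5 without DMSO replicate 2, 6 without ascorbate replicate 1 and 4 without ascorbate replicate 2. The stress response count by limma was 0 (16 unadjusted), 1, 2 and 1 without those libraries in that order.

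With ascorbate present in both arms, TETi76 raised OSGIN1 from 2.02 ± 0.638 to 77.0 ± 3.49 FPKM (log2 4.70, SE 0.17, adjusted p = 3.96e-07) and the secreted chaperone CLU from 0.177 ± 0.251 to 20.1 ± 2.73 (log2 4.18, SE 0.28). LUCAT1 was listed at 0 with ascorbate alone and reached 14.8 FPKM. CHAC1 (log2 -3.01, SE 0.17), the globin gene HBQ1 (log2 -2.75, SE 0.21) and the histone gene HIST2H3D (log2 -2.73, SE 0.58) fell. KLF1 fell from 75.5 ± 3.47 to 16.3 ± 2.64 FPKM. limma called 3841 genes, 1609 higher and 2232 lower. At 2-fold 402 were higher and 364 lower, and the split was 1851 and 1951 with median-ratio scaling and 1790 and 1846 with quantile normalization. Of the lists, 7 passed with an estimated correlation. NRF2 targets had 14 of 19 members higher and 1 lower, immediate early genes 13 of 20 and 1, and the integrated stress response 4 higher and 16 lower of 23. S phase had 22 of 25 lower, cholesterol synthesis 19 of 23 lower and 1 higher, and erythroid genes 13 of 22 lower (adjusted p = 0.0161 for each of these 6). Oxidative phosphorylation had 14 of 23 lower (adjusted p = 0.0225). A further 6 lists passed at the preset correlation alone. Among them the heat-shock list had 7 higher and 3 lower of 17, with a median of 0.08 (adjusted p = 0.0862 with an estimated correlation). TET1 was lower (log2 -0.61, SE 0.13, adjusted p = 0.00718), but not in a fit of those groups alone (adjusted p = 0.0551), whereas TET2 and TET3 stood at log2 0.20 (adjusted p = 0.536) and 0.01 (adjusted p = 0.978).

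Adding ascorbate to TETi76 changed few genes. CDKN1A (log2 1.01, SE 0.11, adjusted p = 0.0107) and HSPA1A (log2 0.94, SE 0.12, adjusted p = 0.0128) were higher than with TETi76 alone. HBQ1 (log2 -1.88, SE 0.21), KLF1 (log2 -0.94, SE 0.12), the growth regulator MYC (log2 -0.59, SE 0.06) and the transferrin receptor TFRC (log2 -0.54, SE 0.06) were lower. limma called 90 genes, 30 higher and 60 lower (34 and 33 without a filter), with 1830 at an unadjusted p under 0.05. The count was 2 without TETi76 replicate 1, 2 without TETi76 replicate 2 and 3 without replicate 2 of TETi76 with ascorbate. Of 10 lists called at the preset correlation, 6 passed with an estimated correlation (adjusted p = 0.0433 each). NRF2 targets and immediate early genes pointed up with 0 members called by limma and 10 and 4 at an unadjusted p under 0.05. The stress response list pointed up with 2 higher, and mitosis, MYC and erythroid lists pointed down with 2, 2 and 3 lower. TET1, TET2 and TET3 stood at log2 -0.06, 0.07 and 0.12 (adjusted p = 0.885, 0.937 and 0.782).

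The interaction asked whether ascorbate altered the effect of TETi76. For CTH the TETi76 effect was higher with ascorbate than without (difference in log2 1.83, SE 0.20, adjusted p = 0.0109), as for PSAT1 (1.24, SE 0.12) and the cystine transporter SLC7A11 (1.17, SE 0.19). PSAT1 stood at 24.5 ± 1.70 FPKM with both compounds and 20.2 ± 0.975 with TETi76 alone, while ascorbate alone had already lowered it. TFRC (-0.93, SE 0.08), KLF1 (-0.94, SE 0.16), MYC (-0.63, SE 0.08) and HIST2H2BC (-2.06, SE 0.31) had lower effects with ascorbate. limma called 79 genes, with 1707 at an unadjusted p under 0.05. Of these, 35 were higher and 44 lower, a split that turned to 34 and 31 with median-ratio scaling, 38 and 26 with quantile normalization, 23 and 19 without a filter and 16 and 11 at 2-fold. The count was 3 and 12 without K01 DMSO replicates 1 and 2, 0 (1542 unadjusted) and 26 without TETi76 replicates 1 and 2, 16 and 0 (1560 unadjusted) without ascorbate replicates 1 and 2, and 37 without replicate 2 of TETi76 with ascorbate. The integrated stress response list had 9 of 23 members higher (16 adjusted over the list alone, median 0.83, adjusted p = 0.00239 with an estimated correlation). Its count was 1 and 2 without K01 DMSO replicates 1 and 2, 0 (18 unadjusted, limma) and 5 without TETi76 replicates 1 and 2, 2 and 0 (17 unadjusted) without ascorbate replicates 1 and 2, and 5 without replicate 2 of TETi76 with ascorbate. The mean of this list was 0.68, and it contains the ascorbate effect without TETi76 (mean -0.55), which uses the K01 DMSO libraries; with TETi76 present the ascorbate effect had a mean of 0.13. MYC and ribosome biogenesis had 2 of 22 lower (adjusted p = 0.0202 with an estimated correlation). For TET1, TET2 and TET3 the difference was -0.21, 0.36 and 0.20 (adjusted p = 0.683, 0.683 and 0.751).

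The effects of TETi76 in SIGM5 and K01 were compared gene by gene. The ATF4 target CHAC1 stood at log2 -0.51 in SIGM5 and -3.83 in K01 (difference 3.33, SE 0.37, adjusted p = 1.47e-07). DDIT4 stood at -0.43 and -3.21 (difference 2.78, SE 0.17), PSAT1 at -0.17 and -2.88 (difference 2.72, SE 0.14) and PLCD1 at 0.26 and -2.61 (difference 2.87, SE 0.30). The metallothionein MT2A fell in SIGM5 (log2 -0.76) and rose in K01 (log2 2.44), a difference of -3.20 (SE 0.21). ID3 had a difference of -2.18 (SE 0.46). Of 9741 genes, 1172 differed, 694 with a higher effect in SIGM5 and 478 with a lower one. The count was 522 and 666 without SIGM5 TETi76 replicates 1 and 2, and 769 without K01 DMSO replicate 2. The integrated stress response list differed in 18 of 22 members (median 1.19, adjusted p = 2.38e-28 by cameraPR, at the preset correlation alone). This rests on the K01 DMSO libraries: the K01 median was -1.42 against them and -0.65 with ascorbate in both arms, beside -0.24 in SIGM5. The S phase list differed in 12 of 25 (17 adjusted over the list alone, median 0.46, adjusted p = 9.68e-10 by the same test). Effects were lower in SIGM5 for 7 immediate early genes with 1 higher of 20 (median -0.45) and for 4 interferon genes of 12 (median -0.77). NRF2 targets split into 5 higher and 6 lower of 17, with median and mean of opposite sign. Without SIGM5 TETi76 replicate 2 the S phase count was 7, without SIGM5 TETi76 replicate 1 the immediate early count was 4, and without SIGM5 DMSO replicate 2 the interferon count was 7. Differences for TET1, TET2 and TET3 were -0.40, 0.22 and 0.24 (adjusted p = 0.394, 0.636 and 0.455). The values of the lines are in different units and came from tables of different kinds, which no term in the fit removes.

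**Figure D4:**
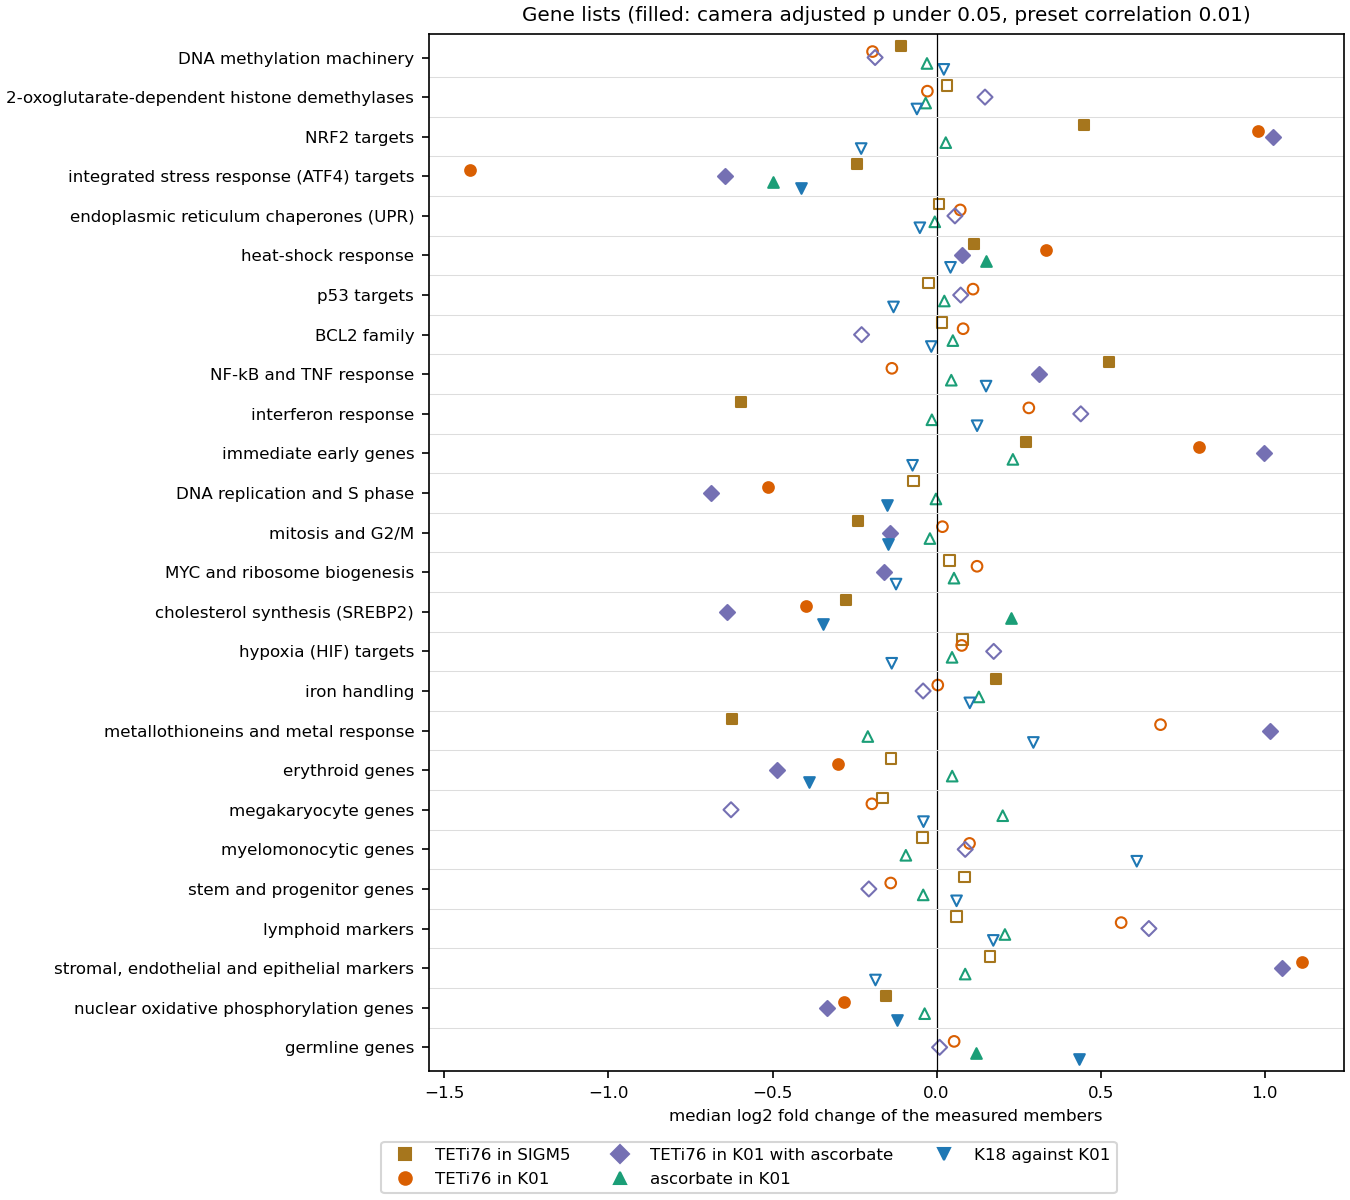
Median log2 fold change of the measured members of each gene list in 5 comparisons, 1 point per list and comparison, filled where camera at the preset correlation gave an adjusted p under 0.05. With an estimated correlation the calls went from 12 to 0 for TETi76 in SIGM5, from 7 to 1 in K18, from 13 to 7 for TETi76 with ascorbate and from 4 to 3 for ascorbate, and stayed at 9 for TETi76 in K01. That test has the fewest degrees of freedom in SIGM5, so the calls lost there need not come from correlated genes. The integrated stress response list lay lowest for TETi76 in K01, at -1.42, against -0.24 in SIGM5.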

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

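The tests of the K01 DMSO level as the cause of the fall under TETi76 and of a persisting TET2 transcript, Fisher's test of K18 against ascorbate and the comparison of on/off genes between pairs of libraries were chosen only after the results were seen.

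The TETi76 effect differed by ascorbate in 79 genes of K01 and between lines in 1172 genes, each by a test of the difference itself. By ascorbate, the differences in log2 effect (with minus without) were 1.83 for CTH, 1.24 for PSAT1, 1.17 for SLC7A11, 1.03 for TRIB3, 1.02 for SESN2 and 0.95 for CEBPG. They were -2.06 for HIST2H2BC, -1.85 for C20orf24, -1.36 for TMEM158, -1.10 for NOP16, -0.94 for KLF1, -0.93 for TFRC, -0.63 for MYC and -0.42 for HBE1.

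Between lines (SIGM5 minus K01) the difference was 3.33 for CHAC1, 2.87 for PLCD1, 2.78 for DDIT4, 2.72 for PSAT1 and 2.06 for MTHFD2, and 1.54 for ICAM1, 1.35 for SLC7A11, 1.35 for CDC45, 1.11 for TNFAIP3 and 1.08 for MCM7. It was -3.20 for MT2A, -2.24 for SLC7A8, -2.18 for ID3, -2.15 for OSGIN1, -2.15 for IFIT3, -1.68 for IRF7 and -1.42 for FOSL1. Further differences were -1.38 for JUN, -1.38 for VIM, -1.29 for SPI1, -1.01 for ISG15 and -0.996 for GCLC. SLC7A8 passed by little (adjusted p = 0.0351) and gave 0.0533 without a filter on low values and 0.171 with DESeq2.

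Short-RNA entries outside the tested genes also changed, out of 228 that passed the filter: 3 under TETi76 (MIR6895, SNORD1C and SNORD63, higher), 3 in K18 (MIR4461 lower, MIR4687 and SNAR-D higher), 1 under ascorbate (SNORD80, lower), 2 under TETi76 with ascorbate (MIR4461 lower, SNORD80 higher) and 3 when ascorbate was added to TETi76 (MIR6895, SNORD1C and SNORD63, lower). These RNAs mostly lack a poly(A) tail and are shorter than the fragments of such libraries, so their values are given without a fold change.

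The first pattern weighed is that integrated stress response genes were lower than in K01 DMSO under TETi76, under ascorbate and in K18, which 2 K01 DMSO libraries with raised expression could produce. As the whole cause of the fall under TETi76 this is excluded, since TETi76 with ascorbate against ascorbate alone, which uses no such library, gave a median of -0.65. For ascorbate and K18 it stays open: 7 of the 23 members differed between K18 and K01 with ascorbate, 5 higher and 2 lower in K18, against 15.6% of other genes (Fisher's exact test, two-sided, p = 0.076). The bound of 5 members set beforehand was too weak, because 1959 of 12527 genes differed between those groups, and the controls cannot be told apart from a shared response. The same doubt covers this list's interaction and its difference between lines, which use those libraries, and a biological effect of ascorbate and of TET2 loss on ATF4 signalling stays open, untested.

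The second pattern is the shift of the interferon, NF-kB and NRF2 lists in SIGM5. A single library as the source of the medians is excluded, since the smallest share of a list's median kept without 1 library was 76.5%. TMM scaling of the counts is excluded too, since with library size alone at least 95.9% of each median was kept. That step moved the median of all genes only from log2 0.00082 to 0.02485, a shift much smaller than these list medians. A filter of 1 CPM in 2 libraries kept 64.4% of the NF-kB median. A response of SIGM5 to TETi76 would give these values but remains a hypothesis, because only 2 libraries per group were compared. No list passed with an estimated correlation, but that test has too few degrees of freedom in SIGM5 to decide this. Library batches are not given in the labels.

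The third pattern is TET2 mRNA that was not lower in the libraries labelled TET2-/-. That these libraries are K01 cells was tested by genes at an FPKM of at least 10 in one clone and under 1 in every library of the other. The 7 found (among them ACTL8, ALOX5, KIT and TUBA3C in K18 and CTAG2 and PTPRC in K01) exceeded the 5 this explanation allows. They fell short of the more than 50 set beforehand to exclude it, so that bound left it open. Counted by pairs of libraries, 13 to 27 genes were on in one and off in the other in the 16 pairs of K18 with K01, and 0 to 12 in the 28 pairs within K01. At only 3 of 6 pairs of FPKM cutoffs, this one included, did every pair with K18 exceed every pair within K01 (at 5 and 1 FPKM the lowest was 59 and the highest 60). Pairs within K01 include treated against untreated libraries. Between DMSO libraries of K18 and K01 at least 13 genes were so found, against at most 5 between replicates. The lowest such pair exceeded the highest replicate pair at all 6 pairs of cutoffs (36 against 16 at 5 and 0.5 FPKM, 4 against 2 at 20 and 1 FPKM). These values argue against the K18 libraries being K01 cells in DMSO, although the replicates may be technical. A disrupted gene whose transcript persists may explain a log2 difference of 0.37, but values per gene cannot decide this, and reads over the edited exon would.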

How the results depend on the processing

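Chosen only after the data were seen were the FPKM filter of 5, crossed replicate pairing, pseudocounts of 0.25 and 5, keeping short RNAs, a joint limma fit, and median-ratio scaling and quantile normalization of the FPKM values; the other alternatives, RLE in SIGM5 among them, were planned. For K562 the planned library-size scaling, CPM filter, DESeq2, voom and RLE were not run because its values are not counts, and the planned joint edgeR fit of both lines was not run for the same reason. Over the alternatives, results for single genes and lists kept their side of the threshold in 2860 values, lost the call in 366 and gained it in 2. No value that passed in the main analysis or in the alternative reversed direction. Changes of sign among values that passed in neither were not counted. Counts and similarities were unchanged by the 1.5-fold criterion or within their error in 105 values, were lower in 49, higher in 6 and moved in 13. At an adjusted p under 0.01 the counts were 210 for TETi76 in SIGM5, 1410 for TETi76 in K01, 824 for K18, 13 for ascorbate, 2082 for TETi76 with ascorbate, 0 for ascorbate added to TETi76, 0 for the interaction and 590 for the difference between lines; the 2 counts of 0 are from limma, with 1830 and 1707 genes at an unadjusted p under 0.05. With an absolute log2 change of at least 1 they were 106, 513, 504, 8, 766, 14, 27 and 296 in that order. In SIGM5 the count was 738 without a filter on low counts and 1291 with replicates paired crosswise; DESeq2 gave 357 and limma-voom 464. The interaction count was 42 without a filter, 136 with an FPKM of at least 5, 46 with a replicate block and 26 with the contrast's groups alone. With those groups alone ascorbate gave 0 by limma (1451 unadjusted) and ascorbate added to TETi76 gave 0 (1397 unadjusted), since fewer libraries estimate the spread. Leaving out 1 library, which assumes that the lone remaining library varies like the others, gave 110 to 1206 for SIGM5, 1663 to 1779 for TETi76 in K01, 783 to 967 for K18, 0 to 6 for ascorbate, 2697 to 2942 for TETi76 with ascorbate, 2 to 62 for ascorbate added to TETi76, 0 to 69 for the interaction and 522 to 1484 for the difference between lines. The similarity of K18 with TETi76 plus ascorbate was 0.145 over genes called in at least 1. That of TETi76 with and without ascorbate was 0.807 at a mean FPKM of at least 10, 0.796 over called genes and 0.636 to 0.653 without 1 library; that between lines was 0.362 over called genes and 0.214 to 0.259 without 1 library. Of 181 list tests, 61 were called by camera at the preset correlation, 28 with an estimated correlation (all 28 among the 61) and 99 by fry, which tests a list by itself (56 among the 61). Median-ratio or RLE scaling called 61 (57 shared). For TETi76 in K01, median-ratio scaling gave 2851 genes (1350 higher) and quantile normalization 2810 (1428 higher, 1382 lower, against 1203 and 1716). The cause of these shifts was not tested except where stated. At 4.71 to 8.96 M reads in K562, genes with an FPKM near 1 have few reads, which limits the calls among them.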

Other observations

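The families below were chosen only after the data were seen; the tests of the synthetases and of the proteasome had their bounds written before their results, and the remaining families had none.

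Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and lie outside the fixed lists, fell under TETi76 in K01 for 16 of 20 members, with a median log2 change of -0.74. They were lower for 14 of 20 in K18, fell in 7 of 20 under ascorbate and in 17 of 20 under TETi76 with ascorbate (adjusted p = 0.0049, 0.0049 and 0.00469 with an estimated correlation). The lower levels in K18 and under ascorbate were measured against the same K01 DMSO libraries, so raised expression in those remains open for them, as for the integrated stress response list. When ascorbate was added to TETi76, limma called 0 of 20, with 6 at an unadjusted p under 0.05 (median -0.07), and in the interaction 4 of 20 were higher (median 0.13, adjusted p = 0.0533 with an estimated correlation and 0.000541 at the preset one). In SIGM5 edgeR called 0 of 19, with 2 at an unadjusted p under 0.05. Proteasome subunits rose in 11 of 31 under TETi76 in K01 and in 19 of 31 under TETi76 with ascorbate (adjusted p = 0.0131 and 0.0106 with an estimated correlation). In SIGM5 edgeR called 0 of 31, with 1 at an unadjusted p under 0.05.

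Other families did not pass with an estimated correlation. Cytosolic ribosomal protein genes had 6 of 60 members lower in SIGM5, 20 of 61 lower under TETi76 in K01, and 1 higher and 20 lower of 61 in K18 (adjusted p = 0.3, 0.314 and 0.185). Subunits of the V-ATPase had 5 higher and 1 lower of 16 under TETi76 in K01 (adjusted p = 0.137), tubulins 4 higher and 1 lower of 10 (adjusted p = 0.137), and autophagy genes 6 higher and 1 lower of 20 under TETi76 with ascorbate (adjusted p = 0.0712). Glycolysis genes had 4 of 14 lower in K18 (adjusted p = 0.116).

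Lower ATF4 activity is a candidate explanation for the fall of integrated stress response genes in K01 under TETi76. If so, the synthetases, which ATF4 is known to induce, should fall too, and they did (camera with an estimated correlation, p = 0.000365). The test does not separate ATF4 from other regulators of both groups.

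Inhibition of protein breakdown may lie behind the joint rise of heat-shock and NRF2 genes in K01. Proteasome subunit genes, which rise together after proteasome inhibition, had a median log2 change of 0.18 (camera with an estimated correlation, p = 0.00375). The rise is small, and general protein damage would give it as well. The test does not separate inhibited protein breakdown from other regulators of these genes, such as NRF2. Under TETi76 with ascorbate the heat-shock list passed camera at the preset correlation (adjusted p = 0.0151). It did not pass with an estimated correlation (adjusted p = 0.0862). The fall of 20 of 23 integrated stress response targets under TETi76 alone in K01 (1 rose, median log2 -1.42) argues against the hypothesis. Blocked protein breakdown would tend to raise these genes. Neither hypothesis was tested outside these libraries.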
